A study of Mus musculus with 11 samples.

How the data were processed

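RNA sequencing covered 11 libraries in 4 groups. Cells carrying green fluorescent protein (GFP) were sorted by flow cytometry from dissociated spinal cords of Col1a1 GFP mice, a reporter strain on the C57BL/6 background in which GFP marks cells that use the collagen I gene Col1a1. The sorted libraries came from healthy mice (sorted control, n = 3) and from mice with experimental autoimmune encephalomyelitis (EAE), an autoimmune model of multiple sclerosis, taken 5 days (D5, n = 3) or 10 days (D10, n = 3) after the first symptoms. Each sorted library pooled 2 to 3 cords, and the design text names these pools as biological replicates. P-values of single genes between sorted groups therefore measure the spread between separate pools of animals. The 2 whole cord libraries each came from the homogenate of 1 cord of a healthy C57BL/6 mouse. Their labels repeat the sorting protocol, while the design text describes unsorted homogenate, and the design text was followed. Replicate numbers were used as names only, since no label says that a number marks a shared litter, batch or day.

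Per the labels' protocols, the libraries were read paired-end at 100 bases on a HiSeq4000. Per the submitters' processing notes, the genome build was mm9 and the tools were TopHat2 (2.0.11), Bowtie2 (2.2.1), SAMtools (0.1.19), HTSeq (0.6.1) and DESeq2. The gene annotation and the use of strand in counting are not given in the sources used here. Reads of overlapping or antisense genes therefore cannot be assigned to a strand, and values of near-identical genes (H2-Q6 and H2-Q7, immunoglobulin segments, histone, Gbp and alpha globin genes) are uncertain. The authors deposited raw counts per gene, counts scaled to library size (CPM) per library and the group means of CPM, per the file headers. Each deposited CPM value equalled the count divided by the summed count of its library to within 1e-09 CPM, so the authors' CPM held no further scaling and was not used for tests. The table held 37991 Ensembl genes and 1 line of column totals, which equalled the column sums and was kept out of library sizes and tests. Of the gene symbols, 24 had been turned into dates by a spreadsheet and were restored through their Ensembl identifiers. A further 3401 genes shared a symbol with a gene of more counts and were kept by identifier. In the GRCm38 annotation, 32919 identifiers were found. It was used for names only, since its build differs from mm9 and no coordinates are given. No library had a count for 11351 genes.

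Counts were tested with the quasi-likelihood test of edgeR (4.0.16, R 4.3.3) after TMM scaling and the default expression filter by group. The 3 sorted groups entered one fit of 9 libraries, and the sorted control was compared with whole cord in a separate fit of 5 libraries. CPM values in the text are TMM-scaled within each fit, given as mean ± SD, so that the sorted control has slightly different CPM values in the 2 fits. Log2 fold changes are given with a standard error (SE) derived from the test statistic. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and a gene was called at an adjusted p under 0.05. Gene lists (44, covering fibroblast and matrix genes, signalling, metabolism, cell cycle, immune pathways, markers of other cell types and RNA quality) were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 43 lists that had at least 5 tested members. The B and plasma cell list had fewer and was not tested. The tests, the lists and the rule for named genes were fixed before the data were examined. A list adjusted p without further words is the camera value. At the preset correlation camera treats list members as nearly independent, so this p-value does not measure the spread between pools. With a correlation estimated from the residuals no list passed in any comparison, and those p-values stand beside the calls. The fry test asks only whether the members of a list move together, without comparing them with other genes.

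Named genes were those with the largest changes (5 in each direction, called, at least 10 CPM in the higher group and no overlap between groups), the 2 members with the largest change in each called list (called, at least 5 CPM), 11 genes reported in every comparison, and the most abundant tested member of each cell type list. Not every gene that this rule names is reported here. For these genes all libraries of one group lay above or below all libraries of the other unless values show otherwise. Exceptions among called genes at D10 were Mmp3, Rrm2 and Il11. A fold against a group with 0 counts was computed against a floor of 3 counts over the group, and a ratio with 1 to 3 counts has a 95% counting interval. These intervals and floors cover counting error only.

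Library totals ran from 7123291 to 12238751 counts. The method was tested on simulated counts drawn from the real means and library sizes. Of 100 genes changed by a fold of 2, 29% were recovered for sorted control against whole cord, 35% for D5 against control, 34% for D10 against control and 26% for D10 against D5. For a fold of 4 the shares were 56%, 71%, 69% and 69%. False calls made up 8.60%, 4.50%, 5.50% and 4.04% of calls in the same order. Beyond the genes changed by a fold of 2 or 4, all simulated genes were unchanged. This gave 93 to 111 calls, against 9208, 3817, 2136 and 21 real calls in that order. How easily a gene passes depends on how many others do, so these shares cannot give the recovery in the real data. Over 40 random lists, camera called 0, 1, 0 and 0, and it called the list with raised genes in each comparison. The simulated genes varied independently of each other, so this cannot show how camera treats lists whose members move together. Alternatives were DESeq2 size factors, upper quartile scaling, no filter, a filter of 10 counts, the DESeq2 Wald test (1.42.0), limma voom, all 11 libraries in one fit, only the groups compared, the replicate number as a block, an adjusted p under 0.01, and leaving out each library in turn. An alternative without mmu-mir-689-2, mt-Rnr1 and mt-Rnr2, which hold a large share of the counts, was added after seeing the data. The list gene H2-L was not analysed here.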

Results

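Gene expression was measured by RNA sequencing in Col1a1 GFP cells sorted from the spinal cord in health and at 5 and 10 days after EAE onset, beside homogenate of whole healthy cord. The 3 sorted control libraries held 7943615 to 10300867 counts and the 3 D5 libraries 7123291 to 8485996. The 3 D10 libraries held 8970221 to 10491064 counts and the 2 whole cord libraries 9091545 to 12238751. The share of counts in the mitochondrial ribosomal genes mt-Rnr1 and mt-Rnr2 was 3.82% ± 0.229 in sorted control, 6.31% ± 0.690 at D5, 4.56% ± 0.480 at D10 and 15.8% ± 2.10 in whole cord (SD). Mitochondrial messenger RNA took 0.567% ± 0.0843, 0.604% ± 0.0342, 0.501% ± 0.0464 and 1.54% ± 0.110 in the same order.

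Along the first principal component of the 9 sorted libraries, which held 48.8% of the variance, controls lay between -81.6 and -78 and D5 libraries between 51.9 and 59.2. D10 replicates 1 and 2 lay between these groups at 12 and 3.4, while D10 replicate 3 lay at 53.8, within the range of the D5 libraries.

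**Figure D1:**
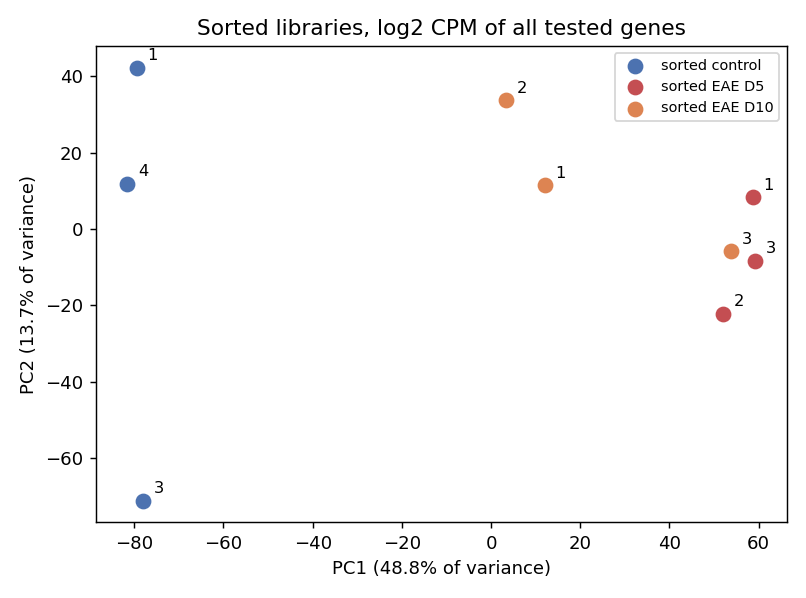
Principal components 1 (x axis, 48.8% of variance) and 2 (y axis, 13.7%) of log2 CPM over all tested genes in the 9 sorted libraries, with 1 point per library, coloured by group and numbered by replicate. D10 replicate 3 (53.8) sits among the D5 points, and the other D10 libraries (12 and 3.4) sit between D5 and control.

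The first comparison asked how the healthy sorted cells differ from homogenate of whole cords of other healthy mice. Only the sorted cells were dissociated, sorted and pooled, so effects of preparation cannot be told apart from those of cell identity. Genes of connective tissue fibroblasts were far higher in the sorted cells. Col1a1 (ENSMUSG00000001506), which encodes the main chain of collagen I and drives the reporter, stood at 6665 ± 1575 CPM in sorted control (n = 3) and 55.7 ± 29.6 CPM in whole cord (n = 2), a log2 fold change of 6.90 ± 0.46 (SE, adjusted p = 1.61e-05). The small proteoglycans Dcn (8.07 ± 0.62, adjusted p = 3.03e-05) and Lum (7.52 ± 0.51, adjusted p = 1.68e-05) were likewise higher. So were the transcription factor Tbx18 (6.99 ± 0.22, adjusted p = 1.27e-06) and the eosinophil chemokine Ccl11 (9.88 ± 0.41, adjusted p = 2.32e-06). Without whole cord replicate 1 the log2 value was 7.40 for Dcn, 6.84 for Lum and 9.07 for Ccl11, and without whole cord replicate 3 it was 9.32, 9.05 and 13.96, with 7.55 for Col1a1. In the opposite direction, the astrocyte glutamate transporter Slc1a2 was 319-fold lower and the neurofilament gene Nefm 615-fold lower. Of 16562 genes tested with edgeR's quasi-likelihood test, 4462 were higher and 4746 lower in sorted cells at an adjusted p under 0.05, of which 3465 and 3783 differed by a fold of at least 2. The total of 9208 dropped to 5973 when whole cord replicate 1 was left out, which leaves 1 cord library.

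Among genes at 0 counts in 1 group, the dipeptidase gene Dpep1 was at least 152-fold higher in sorted cells, the collagenase Mmp13 at least 133-fold, Il6 at least 107-fold, Fam71a at least 183-fold and the unnamed gene Gm17589 at least 327-fold. Il6 and Fam71a varied between sorted libraries (16.7 ± 12.4 and 29.4 ± 23.1 CPM). With limma voom both calls ended (adjusted p = 0.0969 and 0.276), the highest values among the alternatives, of which the lowest were 2.13e-08 and 1.06e-05. The vesicular GABA transporter Slc32a1 was at least 823-fold lower in sorted cells, the sialyltransferase St8sia3 at least 576-fold, the glypican Gpc5 at least 402-fold, the potassium channel Kcnk9 at least 364-fold and 2810011L19Rik at least 351-fold.

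All 24 fibroblast identity genes tested were higher in sorted cells (24 adjusted over the list alone, median log2 6.30, list adjusted p = 2.45e-24). Of 20 leptomeningeal genes 18 were higher and 1 lower (18 and 1 over the list alone, median 4.31, list adjusted p = 4.09e-11). Among matrix genes, 29 of 31 fibrillar collagen and processing genes (2 lower, 29 and 2 over the list alone) and 17 of 20 basement membrane genes (1 lower, 17 and 1) were higher, with medians of 3.54 and 5.16. So were 28 of 31 matricellular glycoproteins (0 lower, 28 and 0) and 22 of 28 matrix proteases and inhibitors (3 lower, 23 and 3), with medians of 4.55 and 2.88. Col15a1 and Lama2 of the basement membrane stood at 3481 ± 380 and 2729 ± 176 CPM against 16 ± 9.67 and 25.6 ± 6.72 in whole cord (Col15a1 log2 7.74, or 8.53 without whole cord replicate 3). Signalling lists were also higher, with 23 of 31 TGF-beta and BMP genes (2 lower, 24 and 2 adjusted over the list alone), 20 of 25 Wnt genes (1 lower, 20 and 1) and 12 of 15 retinoid genes (1 lower, 12 and 1). The same held for 22 of 34 growth factors and receptors (3 lower, 24 and 4) and 12 of 22 solute transporters (3 lower, 12 and 3). Bmp5, a bone morphogenetic protein, was 96.4-fold higher and Aldh1a2, which makes retinoic acid, 45.3-fold. Their log2 values of 6.59 and 5.50 became 5.98 and 4.91 without whole cord replicate 1 and 7.92 and 6.66 without whole cord replicate 3. With an estimated correlation the adjusted p was 0.115 for each of these lists except basement membrane, where adjusted p = 0.128 with an estimated correlation.

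Immune and stress lists were higher in healthy sorted cells than in whole cord, with 20 of 27 interferon gamma response genes (0 lower, 20 and 0 adjusted over the list alone, median log2 2.38), 16 of 22 class I antigen presentation genes (1 lower, 16 and 1, 1.61) and 21 of 24 type I interferon genes (1 lower, 21 and 1, 2.53). Higher too were 16 of 21 cytokines and chemokines (1 lower, 17 and 1, 3.02) and 16 of 19 NF-kB and acute phase genes (1 lower, 16 and 1, 3.91, or 3.46 with genes at 0 counts set to their bound). The other lists of this kind had 9 of 18 complement genes (5 lower, 9 and 5, 1.40), 17 of 26 adhesion genes (4 lower, 17 and 4, 1.74) and 17 of 20 genes of the unfolded protein response (2 lower, 17 and 2, 1.25) higher. The adjusted p ran from 0.115 to 0.261 with an estimated correlation in these lists. The cytokine signalling inhibitor Socs3, which also counts among the immediate-early and heat shock genes, was 293-fold higher and the adhesion molecule Icam1 71.8-fold. Beside these lists, 22 of 23 immediate-early and heat shock genes, which respond to tissue dissociation, were higher and 1 lower (22 and 1 adjusted over the list alone, median log2 5.17, list adjusted p = 4.18e-14, adjusted p = 0.248 with an estimated correlation). Cholesterol synthesis genes were lower (16 of 19 with 1 higher, 16 and 1 adjusted over the list alone, median log2 -1.29, list adjusted p = 0.0198, adjusted p = 0.234 with an estimated correlation). The glycolysis list (7 higher, 14 lower of 24, list adjusted p = 0.171) and the axon guidance list (11 higher, 11 lower of 26, list adjusted p = 0.411) were not called, and axon guidance had a negative median (-0.30) and a positive test direction. Also not called were S phase genes (8 higher, 2 lower of 28, 8 and 1 over the list alone, list adjusted p = 0.171) and G2/M genes (3 higher, 1 lower of 21, 1 and 1 over the list alone, list adjusted p = 0.733).

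Markers of neural cells were lower in sorted cells, with all 18 neuronal genes (18 adjusted over the list alone, median log2 -7.10, list adjusted p = 8.15e-28) and 14 of 15 oligodendrocyte genes (1 higher, 14 and 1, -8.18, list adjusted p = 1.58e-19). The 12 oligodendrocyte precursor genes (12, -3.26) and 11 of 15 astrocyte genes (3 higher, 11 and 3, -4.17) were lower as well. The adjusted p was 0.0509 with an estimated correlation for neurons and 0.115 for the other lists. Markers of mural cells, the contractile cells of vessel walls, were higher (12 of 14, 12 adjusted over the list alone, median log2 3.13, list adjusted p = 2.42e-06, adjusted p = 0.242 with an estimated correlation). The smooth muscle myosin Myh11 stood at 1511 ± 552 against 31.2 ± 25.9 CPM (log2 5.58, or 4.90 without whole cord replicate 1 and 6.84 without 3). Also higher were 21 of 22 contractile and myofibroblast genes (1 lower, 21 and 1, 4.51, adjusted p = 0.197 with an estimated correlation). Endothelial markers went both ways (2 higher, 8 lower of 18, list adjusted p = 0.67), and the endothelial cadherin Cdh5 was 9.18-fold higher (206 ± 15.8 against 22.3 ± 6.04 CPM). Leukocyte lists were not called. The leukocyte phosphatase Ptprc stood at 3.10 ± 2.71 against 5.01 ± 2.11 CPM (adjusted p = 0.447, or 0.0408 and lower in sorted cells without sorted control replicate 1), and the macrophage receptor Csf1r was 7.21-fold lower. Of the other markers, 10 of 18 microglia and macrophage genes were lower and 1 higher (list adjusted p = 0.134, called lower without sorted control replicate 3, 0.0440, or whole cord replicate 1, 0.0354). Lower were also 3 of 12 pan-leukocyte (1 higher, list adjusted p = 0.656) and 2 of 5 T cell genes (0.66), and the T cell list had a positive median (1.24) and a negative mean (-0.86). Of 11 neutrophil and monocyte genes 1 was higher (0.457). Adjusted over the list alone, 2 microglia and macrophage genes were higher and 10 lower, and the counts of the pan-leukocyte, T cell, neutrophil and endothelial lists were as given. Class II presentation genes were not called (2 higher, 1 lower of 11, 0 and 1 over the list alone, list adjusted p = 0.733). Cd74, the class II invariant chain, stood at 10.3 ± 5.62 against 2.83 ± 1.23 CPM, and its call (adjusted p = 0.0336) was lost without sorted control replicate 1 (0.0574) or 3 (0.0640) or whole cord replicate 1 (0.203) or 3 (0.0686) and with limma voom (0.114, with 0.203 the highest among the alternatives). Of the remaining markers, 5 of 12 Schwann cell genes were higher and 4 lower (list adjusted p = 0.473), 1 of 6 ependymal genes was higher and 2 lower (0.859), and 1 of 7 erythroid genes was higher and 2 lower (0.763, 0 and 0 over the list alone). The ependymal list had a negative median (-2.57) and a positive test direction. Cartilage and bone genes (8 higher, 1 lower of 12, list adjusted p = 0.066) were called higher without sorted control replicate 1 (0.0166) or 4 (0.0429) or whole cord replicate 1 (0.0381) or 3 (0.0466). Of the RNA quality lists, all 12 mitochondrial genes were lower (12 over the list alone, median -1.96, list adjusted p = 1.66e-05, adjusted p = 0.287 with an estimated correlation). Ribosomal protein genes were higher (22 of 30, 22 over the list alone, 0.63, list adjusted p = 0.00477, adjusted p = 0.234 with an estimated correlation).

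The second comparison asked how the sorted cells changed 5 days after EAE onset. Of fibrillar collagen and processing genes 15 of 31 rose, as did 32 of 36 G2/M and 24 of 29 interferon gamma response genes, while 12 of 19 cholesterol synthesis genes fell. For these lists adjusted p ran from 0.193 to 0.486 with an estimated correlation. Col1a1 was 15820 ± 3163 CPM at D5 against 7098 ± 1679 in control (n = 3 each), a log2 fold change of 1.16 ± 0.30 (adjusted p = 0.0147). Fibronectin (Fn1, ENSMUSG00000026193) rose from 792 ± 166 to 3180 ± 170 CPM (2.01 ± 0.19, adjusted p = 6.59e-05) and the matricellular protein periostin (Postn, ENSMUSG00000027750) from 39.3 ± 9.75 to 205 ± 19.9 CPM (2.38 ± 0.32, adjusted p = 0.000291). Mki67 (ENSMUSG00000031004), a marker of cycling cells, rose from 31.2 ± 14.8 to 238 ± 4.46 CPM. Of 15972 genes tested with edgeR's quasi-likelihood test, 2115 rose and 1702 fell, of which 1323 and 964 changed by a fold of at least 2. The 3 libraries of each group did not overlap for 41.9% of genes, against 10% by chance. The count of 3817 ran from 2446 (without D5 replicate 3) to 3588 when single libraries were left out.

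Of the collagen chains, Col3a1 (ENSMUSG00000026043) rose 2.50-fold (adjusted p = 0.00568) and Col1a2 (ENSMUSG00000029661) 1.80-fold (adjusted p = 0.0365). The Col1a1 call was lost without control replicate 1 (0.0644) or D5 replicate 3 (0.0595). The Col1a2 call was lost without control replicate 1 (0.132), 3 (0.0546) or 4 (0.0786) or D5 replicate 1 (0.0890) or 3 (0.127) and in a fit of all 11 libraries (0.0524, with 0.132 the highest among the alternatives). In the fibrillar collagen and processing list 15 of 31 genes rose and 3 fell (18 and 3 adjusted over the list alone, median log2 0.51, list adjusted p = 0.000427, adjusted p = 0.486 with an estimated correlation). The procollagen protease Bmp1 was 4.92-fold and the cross-linking enzyme Lox 4.29-fold higher. Matrix proteases and inhibitors rose (11 of 31 with 2 lower, 14 and 4 adjusted over the list alone, median 0.52, list adjusted p = 0.000227, adjusted p = 0.222 with an estimated correlation). The stromelysin Mmp10 was at least 318-fold and the macrophage elastase Mmp12 at least 64.4-fold higher. Matricellular glycoproteins also rose (12 of 31 with 6 lower, 14 and 8 over the list alone, list adjusted p = 0.0372, adjusted p = 0.477 with an estimated correlation). The hyaluronan synthase Has2 was 11.7-fold and the secreted glycoprotein Cthrc1 10.6-fold higher (Has2 log2 3.55, or 4.78 without control replicate 4). The list call was lost without control replicate 1 (0.0764) or 3 (0.117). Basement membrane genes fell as a list (5 rose, 7 fell of 19, 6 and 10 over the list alone, median -0.47, list adjusted p = 0.0339, adjusted p = 0.572 with an estimated correlation). The laminins Lamc3 (655 ± 106 to 182 ± 16.1 CPM) and Lama2 (2906 ± 213 to 873 ± 117 CPM) fell most. The list call was lost without control replicate 3 (0.115) or D5 replicate 1 (0.105).

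Fibroblast identity genes went both ways (8 rose, 11 fell of 24, 8 and 12 adjusted over the list alone, list adjusted p = 0.218). So did leptomeningeal genes (1 rose, 6 fell of 20, 2 and 8 over the list alone, list adjusted p = 0.0574, called lower without control replicate 3, 0.0305, or D5 replicate 1, 0.0199). The largest falls were in Myoc, which encodes the secreted protein myocilin (166 ± 20.7 to 8.97 ± 8.71 CPM, 18.6-fold) and the kinase gene Wnk2 (341 ± 104 to 21.1 ± 10.3 CPM, 16.2-fold). The glucose-responsive transcription factor Mlxipl (15.8-fold), the cystathionine synthase Cbs (14.9-fold) and the potassium channel Kcnk1 (14.8-fold) followed. The adjusted p of these 5 genes lay between 7.72e-05 and 0.00859. The log2 value went from -4.21 to -5.20 for Myoc without D5 replicate 2 and from -3.98 to -4.88 for Mlxipl without D5 replicate 1. Solute transporters fell (8 of 23 with 1 higher, 9 over the list alone, median log2 -0.67, list adjusted p = 0.00639, adjusted p = 0.36 with an estimated correlation). The lipid transporter Abca8a went from 1151 ± 134 to 107 ± 52.5 CPM. Cholesterol synthesis fell in 12 of 19 genes and rose in 0 (14 adjusted over the list alone, median -1.33, list adjusted p = 4.62e-09, adjusted p = 0.222 with an estimated correlation). The desaturase Sc5d fell 5.52-fold. In the retinoid list 6 of 14 genes rose and 2 fell (6 and 3 over the list alone, list adjusted p = 0.0339, adjusted p = 0.313 with an estimated correlation, lost without control replicate 3, 0.104, or D5 replicate 1, 0.0765). The retinol dehydrogenase Rdh10 was 5.58-fold and Aldh1a2 4.13-fold higher.

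G2/M genes rose in 32 of 36 tested (33 adjusted over the list alone, median log2 2.95, list adjusted p = 3.29e-23, adjusted p = 0.193 with an estimated correlation). The mitotic kinesin Kif2c was 33.2-fold higher. S phase genes rose in 13 of 29 (16 over the list alone, 1.06, list adjusted p = 7.39e-05, adjusted p = 0.36 with an estimated correlation), and the ribonucleotide reductase subunit Rrm2 was 9.37-fold higher (log2 3.23, or 3.94 without control replicate 1). Beside these cell division genes, T cell and pan-leukocyte markers had medians of 5.83 and 3.60. Interferon gamma response genes rose in 24 of 29 (24 over the list alone, 2.09, list adjusted p = 2.42e-19). Type I interferon genes rose in 16 of 29 with 1 lower (16, 0.95, list adjusted p = 9.61e-07) and class I presentation genes in 14 of 22 (15, 0.84, list adjusted p = 2.07e-12). For these 3 lists adjusted p = 0.211 with an estimated correlation. The chemokine Cxcl9 was 29.0-fold and the nucleic acid sensor Zbp1 20.9-fold higher. H2-K1 (ENSMUSG00000061232), a class I heavy chain, rose from 236 ± 45.1 to 503 ± 76.3 CPM. H2-Q7 was 23.1-fold higher (log2 4.53, or 5.23 without control replicate 4), a value that is uncertain because H2-Q6 is nearly identical. Class II presentation genes rose in 9 of 13 (11 over the list alone, 2.91, list adjusted p = 3.13e-09, adjusted p = 0.193 with an estimated correlation). Cd74 (ENSMUSG00000024610) went from 11 ± 6.08 to 199 ± 63.9 CPM.

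Complement (7 of 18 higher, 8 higher and 1 lower adjusted over the list alone, list adjusted p = 8e-05, adjusted p = 0.219 with an estimated correlation) and adhesion genes (13 of 27 higher and 3 lower, 15 and 4 over the list alone, list adjusted p = 0.000243, adjusted p = 0.211 with an estimated correlation) rose as lists. Complement C3 went from 70.6 ± 14.8 to 957 ± 146 CPM (13.6-fold) and the hyaluronan receptor Cd44 from 29.8 ± 10.6 to 151 ± 30.6 CPM. Cytokines and chemokines rose in 10 of 28 genes and fell in 2 (14 and 2 over the list alone, list adjusted p = 0.00416, adjusted p = 0.434 with an estimated correlation). The neutrophil chemokine Cxcl5 had a ratio of counts of 117 (95% interval 31.8 to 969, with a fitted log2 of 6.59, or 9.13 without control replicate 4), and the T cell chemokine Ccl22 was at least 172-fold higher. NF-kB and acute phase genes rose in 8 of 20 and fell in 2 (9 and 3 over the list alone, list adjusted p = 0.0207, adjusted p = 0.542 with an estimated correlation, lost without control replicate 3, 0.117, or D5 replicate 1, 0.123). The iron-binding protein Lcn2 was 28.6-fold higher (log2 4.84, or 4.22 without control replicate 4). Lists not called at D5 were TGF-beta and BMP (10 rose, 7 fell of 31, list adjusted p = 0.877), Wnt (8 and 4 of 24, 0.471) and growth factors (8 and 7 of 33, 0.909). The same held for axon guidance (3 and 6 of 26, 0.313), glycolysis (5 and 3 of 24, 0.926) and the unfolded protein response (3 and 2 of 19, 0.936). Adjusted over the list alone these 6 lists had 13 and 9, 10 and 7, 10 and 7, 4 and 6, 5 and 4, and 3 and 2 calls. The median was positive and the test direction negative for growth factors (0.07) and glycolysis (0.06), and for the unfolded protein response the median was 0.21 and the mean -0.01.

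Transcripts of leukocytes rose beside these immune groups. All 14 pan-leukocyte genes rose (14 adjusted over the list alone, median log2 3.60, list adjusted p = 4.11e-18). Ptprc (ENSMUSG00000026395) went from 3.29 ± 2.88 to 56.1 ± 20.2 CPM and the actin bundler Lcp1 from 2.48 ± 2.14 to 62.0 ± 23.7 CPM. For Ptprc the log2 value was 4.13, or 5.08 without control replicate 1, and for Lcp1 4.66, or 5.45 without control replicate 3 and 4.07 without 4. T cell genes rose in 16 of 17 (16 over the list alone, median 5.83, or 5.25 with genes at 0 counts set to their bound, list adjusted p = 8.13e-25). The T cell receptor constant gene Trac and the interleukin receptor Il7r were at least 126-fold and 122-fold higher. For both lists adjusted p = 0.193 with an estimated correlation. Microglia and macrophage genes rose in 11 of 20 (13 over the list alone, 2.01, list adjusted p = 0.0001, adjusted p = 0.299 with an estimated correlation), and lysozyme Lyz2 went from 14.2 ± 11.4 to 111 ± 47.6 CPM (log2 2.99, or 3.62 without control replicate 1). Neutrophil and monocyte genes rose in 5 of 13 (5 over the list alone, 1.97, list adjusted p = 8.88e-05, adjusted p = 0.36 with an estimated correlation). The immunoglobulin gene Ighg1 was at least 502-fold higher (53.1 ± 18.4 CPM), with counts of related segments uncertain. Of these markers 1 of 14 pan-leukocyte, 1 of 18 T cell and 5 of 20 macrophage genes exceeded 5 CPM in sorted control. So did 5 of 16 neutrophil and monocyte genes, a list that includes Fn1. The expression filter also admits genes through the EAE libraries alone, and such genes, near 0 in control, could hardly fall. In this fit 17 T cell and 36 G2/M genes were tested, against 5 and 21 in the fit with whole cord. Counts and medians of these lists are therefore partly set by the filter.

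Vessel wall and neural markers moved less uniformly at D5. Acta2 (ENSMUSG00000035783), smooth muscle actin, stood at 370 ± 120 against 806 ± 384 CPM (-1.12 ± 0.37, adjusted p = 0.0418), a call lost without control replicate 3 (-0.67, 0.175) or 4 (0.0515) or D5 replicate 1 (0.147) or 3 (0.126). Its adjusted p was also 0.084 with the DESeq2 Wald test and 0.0876 in a fit of all 11 libraries, within a range over the alternatives of 3.55e-04 to 0.175. Myh11 fell 3.90-fold (log2 -1.96, or -2.58 without D5 replicate 2, adjusted p = 0.00934). The mural list (4 rose, 3 fell of 14, list adjusted p = 0.515) and the contractile list (6 rose, 9 fell of 22, list adjusted p = 0.233, called lower without control replicate 1, 0.0489) went both ways. Cdh5 rose 2.11-fold while the endothelial list was not called (4 rose, 1 fell of 17, list adjusted p = 0.102). Oligodendrocyte precursor genes (4 of 12 higher, list adjusted p = 0.0593) were called without control replicate 4 (0.0246) or D5 replicate 1 (0.0159). The Schwann cell list (2 rose, 4 fell of 12, list adjusted p = 0.239) was called lower without D5 replicate 2 (0.0136), and its neurotrophin receptor Ngfr fell from 487 ± 222 to 68.6 ± 9.70 CPM. Cartilage and bone genes fell as a list (1 rose, 3 fell of 12, list adjusted p = 0.0279, adjusted p = 0.477 with an estimated correlation, lost without control replicate 4, 0.0806), and the cartilage transcription factor Sox9 fell 2.62-fold. So did erythroid and platelet genes (2 of 7 fell, list adjusted p = 0.0279, adjusted p = 0.477 with an estimated correlation, lost without control replicate 1, 0.115, or D5 replicate 2, 0.0831). Oligodendrocyte (2 and 2 of 11, 0.515), astrocyte (4 and 4 of 15, 0.724), neuron (2 and 2 of 10, 0.565) and ependymal lists (0 and 1 of 5, 0.936) were not called. Adjusted over the list alone, the counts of genes that rose and fell were 5 and 3 for mural, 7 and 9 for contractile, 2 and 3 for oligodendrocyte, 5 and 6 for astrocyte and 2 and 4 for neuron genes, and as above for the other lists of this paragraph. The median was negative and the mean positive for astrocyte (-0.33 and 0.07) and ependymal genes (-0.27 and 0.33). Immediate-early genes were lower as a list (1 rose, 6 fell of 24, median log2 -0.94, list adjusted p = 0.0014, adjusted p = 0.611 with an estimated correlation), with 9 lower over the list alone. Ribosomal protein genes were higher (14 of 30 with 1 lower, 15 and 1 over the list alone, 0.53, list adjusted p = 0.000555, adjusted p = 0.486 with an estimated correlation), and mitochondrial genes were not called (2 of 12 rose, list adjusted p = 0.471).

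**Figure D2:**
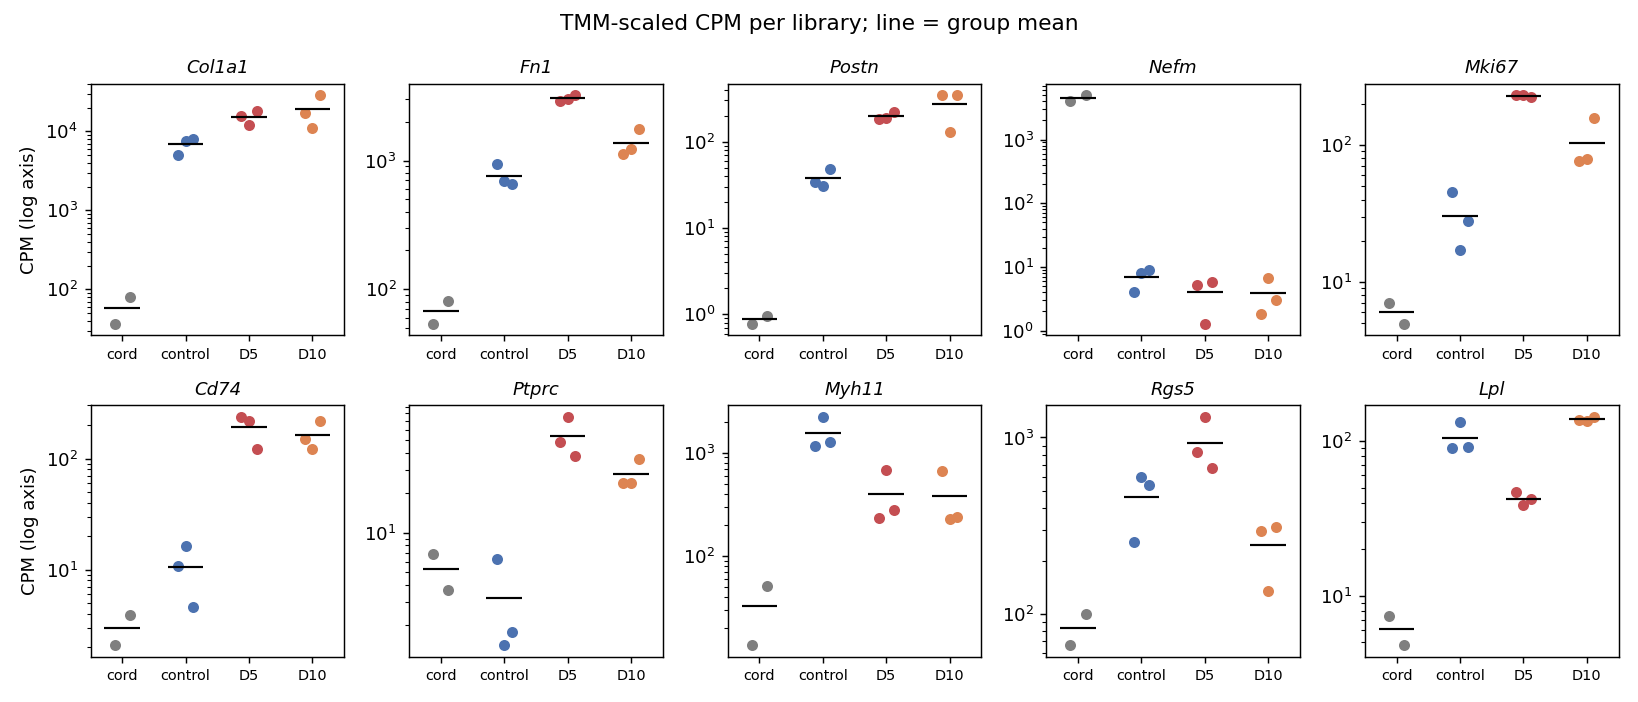
TMM-scaled CPM on a log axis (y) for 10 genes in each library of the 4 groups (x: whole cord, sorted control, D5, D10), with 1 point per library and a line at the group mean. Mki67 lay at 238 ± 4.46 CPM at D5 and 108 ± 46.5 at D10 against 31.2 ± 14.8 in control, and Lpl at 44.1 ± 4.00 at D5 and 144 ± 3.49 at D10.

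The third comparison set the sorted cells 10 days after onset against control. Immunoglobulin transcripts had the largest increases. Of fibrillar collagen and processing genes 14 of 31 rose, as did 19 of 29 interferon gamma response genes, while 8 of 19 cholesterol synthesis genes fell. For these lists adjusted p ran from 0.206 to 0.449 with an estimated correlation. Col1a1 was 19610 ± 9282 CPM against 7098 ± 1679 (1.47 ± 0.30, adjusted p = 0.00806), Postn rose 7.19-fold to 283 ± 128 CPM (adjusted p = 0.000345) and Fn1 1.79-fold to 1419 ± 340 CPM (adjusted p = 0.0120, lost without control replicate 4, 0.0582). Mki67 rose 3.47-fold, Cd74 15.4-fold and H2-K1 1.85-fold. Of 15972 genes tested with edgeR's quasi-likelihood test, 1339 rose and 797 fell, of which 827 and 453 changed by a fold of at least 2. The libraries did not overlap for 31.1% of genes against 10% by chance. The count of 2136 was 1045 without D10 replicate 3, the lowest value, and up to 2031 without other libraries. It was 841 at an adjusted p under 0.01. In a fit of the compared groups alone 797 rose and 687 fell.

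The immunoglobulin gene Ighg1 was at least 695-fold higher at D10, the joining chain Igj at least 379-fold and the variable segment Ighv1-81 at least 183-fold, with a count ratio of 1735 for Ighg2c (interval 593 to 8416). Igkc stood at 378 ± 334 CPM against 0.236 ± 0.261. Without D10 replicate 1 the fitted log2 values of Igj, Ighg2c, Igkc and Ighv1-81 went from 11.48, 10.64, 10.50 and 10.46 to 10.55, 8.33, 9.45 and 7.98. For Ighg2c it was 11.41 without control replicate 4 and for Igkc 11.60 without control replicate 3. With limma voom the adjusted p was 0.0532 for Igj, 0.628 for Ighg2c, 0.0784 for Igkc and 0.177 for Ighv1-81, the highest among the alternatives, whose lowest values were 3.81e-14, 1.02e-10, 8.44e-25 and 7.59e-08. The Ighv1-81 call was also lost without control replicate 4 (0.0533). Segments of this family share sequence, so that single values are uncertain. Pan-leukocyte genes rose in 12 of 14 (14 adjusted over the list alone, median log2 2.88, list adjusted p = 3.24e-16). T cell genes rose in 15 of 17 (16, 4.37, or 4.11 at the bound, list adjusted p = 1.01e-21) and microglia and macrophage genes in 12 of 20 (15, 3.22, list adjusted p = 2.99e-13). For these 3 lists adjusted p = 0.177 with an estimated correlation. Ptprc rose 9.03-fold to 29.0 ± 7.29 CPM and Lyz2 13.7-fold to 192 ± 93.5 CPM. Without control replicate 1 their log2 values of 3.17 and 3.77 became 4.13 and 4.41. Neutrophil and monocyte genes rose in 4 of 13 (5 over the list alone, list adjusted p = 0.000238, adjusted p = 0.391 with an estimated correlation).

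Beside these leukocyte markers, interferon gamma response genes rose in 19 of 29 (24 adjusted over the list alone, median log2 1.56, list adjusted p = 8.43e-15). Class I presentation genes rose in 13 of 22 (16, 0.65, list adjusted p = 1.12e-11) and type I interferon genes in 8 of 29 (11, 0.68, list adjusted p = 3.88e-06). All 3 lists had adjusted p = 0.206 with an estimated correlation. The transcription factor Irf8 rose 11.9-fold (log2 3.58, or 4.30 without control replicate 4) and the oligoadenylate synthetase Oas1a 14.6-fold. Class II presentation genes rose in 6 of 13 (8 over the list alone, 2.33, list adjusted p = 9.75e-10) and complement genes in 9 of 18 (9 and 1 lower, 0.66, list adjusted p = 3.99e-09), each with adjusted p = 0.177 with an estimated correlation. The complement gene C1qa stood at 21.1 ± 7.83 against 0.905 ± 0.930 CPM and the class II chain H2-Ab1 at 64.3 ± 16.6 against 3.46 ± 2.86 CPM. Their log2 values were 4.54 and 4.21, or 5.71 and 5.15 without control replicate 3, and 3.92 for C1qa without control replicate 4. C1qa also belongs to the macrophage list. Cytokines and chemokines rose in 13 of 28 and fell in 2 (15 and 2 over the list alone, list adjusted p = 0.00015, adjusted p = 0.27 with an estimated correlation). NF-kB genes rose in 9 of 20 and fell in 2 (11 and 2, list adjusted p = 0.00107, adjusted p = 0.391 with an estimated correlation). Adhesion genes rose in 10 of 27 and fell in 4 (12 and 4, list adjusted p = 0.00203, adjusted p = 0.206 with an estimated correlation). The integrin Itgb8 rose 3.83-fold. Lcn2 rose 8.73-fold, a call lost without D10 replicate 3 (log2 2.09 against 3.13, 0.101), and its log2 was 2.52 without control replicate 4. It was also lost with limma voom, with the DESeq2 Wald test and in a fit of the compared groups alone, and over all alternatives the adjusted p of Lcn2 ran from 8.65e-07 to 0.101.

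In the matrix, 14 of 31 fibrillar collagen and processing genes rose at D10 and 0 fell (16 and 1 adjusted over the list alone, median log2 0.51, list adjusted p = 9.46e-05, adjusted p = 0.449 with an estimated correlation). The cross-linking enzyme Loxl1 rose 3.58-fold and Col3a1 2.47-fold. Col1a2 rose 2.06-fold, a call lost without control replicate 1 (0.0896) or 4 (0.0614) or D10 replicate 3 (0.62, 0.0878). Matrix proteases and inhibitors rose in 13 of 31 and fell in 1 (15 and 3 over the list alone, list adjusted p = 3.91e-06, adjusted p = 0.177 with an estimated correlation). The protease inhibitor Timp1 stood at 138 ± 141 against 3.30 ± 1.97 CPM (log2 5.38, or 4.16 without D10 replicate 3), and its call ended with limma voom (adjusted p = 0.0631, the highest among the alternatives, with a lowest of 1.33e-12). Retinoid genes rose in 5 of 14 with 1 lower (5 and 1 over the list alone, list adjusted p = 0.0172, adjusted p = 0.206 with an estimated correlation, lost without control replicate 3, 0.0882, or D10 replicate 2, 0.0609), and Aldh1a2 was 3.63-fold higher. G2/M genes rose in 17 of 36 (23 over the list alone, 1.64, list adjusted p = 8.39e-12, adjusted p = 0.206 with an estimated correlation). S phase genes rose in 6 of 29 (9, 0.51, list adjusted p = 0.00634, adjusted p = 0.514 with an estimated correlation, lost without D10 replicate 3, 0.0917), beside medians of 4.37 and 2.88 for T cell and pan-leukocyte markers. The fibroblast identity (8 rose, 3 fell of 24, 8 and 3 over the list alone, list adjusted p = 0.25), basement membrane (8 and 4 of 19, 9 and 6, 0.25) and matricellular lists (10 and 6 of 31, 14 and 7, 0.25) were called higher without D10 replicate 2 (0.0205, 0.00793 and 0.0148). The leptomeningeal list (1 and 3 of 20, 2 and 6 over the list alone, 0.137) was called lower without control replicate 3 (0.0452) or D10 replicate 2 (0.0148).

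Contractile and myofibroblast genes fell in 11 of 22 with 1 higher (12 and 2 adjusted over the list alone, median log2 -0.61, list adjusted p = 3.78e-05). Mural genes fell in 6 of 14 with 1 higher (8 and 1, -0.84, list adjusted p = 0.000142). For both lists, which share Acta2, Myh11, Tagln and Des, adjusted p = 0.391 with an estimated correlation. Acta2 fell 3.53-fold to 228 ± 102 CPM (adjusted p = 0.00767), and Myh11 4.08-fold (log2 -2.03, or -2.74 without D10 replicate 1), lost without D10 replicate 3 (0.0586). Cholesterol synthesis genes fell in 8 of 19 (13 over the list alone, -1.08, list adjusted p = 1.24e-07, adjusted p = 0.206 with an estimated correlation). Solute transporters fell in 6 of 23 with 1 higher (8 over the list alone, list adjusted p = 0.0108, adjusted p = 0.391 with an estimated correlation). Among single genes, Myoc (8.48-fold), the collectin Colec11 (8.39-fold), the adhesion molecule Cntn3 (8.01-fold), the glutamate receptor Gria1 (7.85-fold) and Wnk2 (7.85-fold) fell most. Without D10 replicate 2 the log2 value went from -3.08 to -4.60 for Myoc, -3.00 to -4.07 for Cntn3, -2.97 to -4.00 for Gria1 and -2.97 to -3.69 for Wnk2. The Myoc call was lost without control replicate 4 (0.0539) or D10 replicate 1 (0.0596) or 3 (0.0575). Oligodendrocyte precursor genes rose in 7 of 12 (8 over the list alone, 1.32, list adjusted p = 0.000130, adjusted p = 0.206 with an estimated correlation). Of the quality lists, ribosomal protein genes were higher (3 of 30, 9 over the list alone, list adjusted p = 0.00496, adjusted p = 0.564 with an estimated correlation) and immediate-early genes showed 0 calls of 24 (list adjusted p = 0.33, called lower without control replicate 3, 0.00952, or D10 replicate 2, 0.0333).

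Signalling and metabolic lists not called at D10 were TGF-beta and BMP (8 rose, 3 fell of 31, list adjusted p = 0.319), Wnt (5 and 1 of 24, 0.271) and growth factors (9 and 4 of 33, 0.434). Axon guidance (2 and 2 of 26, 0.456), glycolysis (0 and 2 of 24, 0.543) and the unfolded protein response (4 and 0 of 19, 0.161, called higher without D10 replicate 1, 0.0127) were not called either. Adjusted over the list alone these lists had 11 and 6, 6 and 2, 10 and 5, 3 and 6, 0 and 1, and 7 and 1 calls. Among markers of other cells, endothelial (4 and 2 of 17, 0.252), oligodendrocyte (1 and 1 of 11, 0.439) and astrocyte genes (4 and 2 of 15, 0.271) were not called. Neuronal genes (2 and 1 of 10, 0.249) were called lower without control replicate 1 (0.0371). The same lack of a call held for Schwann cell (2 and 1 of 12, 0.456), cartilage and bone (1 and 0 of 12, 0.931), erythroid (0 and 0 of 7, 0.949), ependymal (1 and 1 of 5, 0.995) and mitochondrial genes (0 and 0 of 12, 0.813). Over the list alone, oligodendrocyte genes had 2 and 1 calls and Schwann cell genes 6 and 2, and the other marker lists had the counts given. The ependymal median (-0.40) and mean (0.02) differed in sign, and mitochondrial genes had a positive median (0.02) and a negative test direction. Ngfr fell 4.41-fold to 110 ± 21.7 CPM and Cdh5 rose 1.80-fold to 393 ± 26 CPM.

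**Figure D3:**
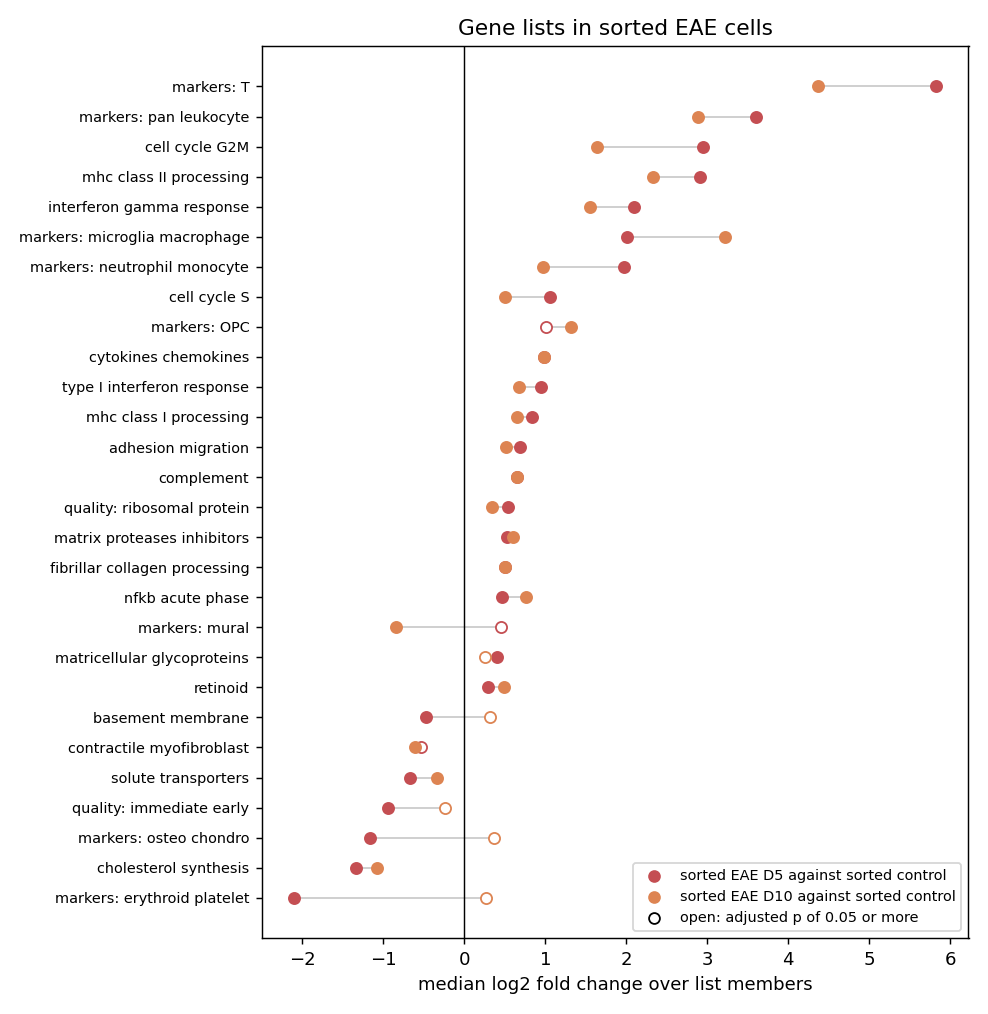
Median log2 fold change over control (x) of 28 gene lists (y) at D5 and D10, with filled points for lists at an adjusted camera p under 0.05 and open points for the others. T cell markers (5.83 and 4.37) lie farthest to the right at both times, pan-leukocyte markers lie at 3.60 and 2.88, and cholesterol synthesis (-1.33 and -1.08) is negative at both times.

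The responses at D5 and D10 shared 1201 of the genes that rose (chance for independent lists 177) and 668 of those that fell (chance 84.9), which was 89.7% and 83.8% of the D10 calls. Both comparisons use the same controls. Over 20 simulations of unchanged groups against them at most 1 call was shared. Few genes can pass in unchanged groups, so this count cannot show how many shared calls the controls add when both groups change. The covariance of the log2 fold changes was 1.26, against a simulated mean of 0.0990, a difference of 1.16. With 3 controls these could not be split, so part of the excess overlap may come from shared controls. The total of 1869 shared calls, beside 2136 calls at D10, was 951 without D10 replicate 3, beside 1045 calls at D10. At an adjusted p under 0.01 it was 738, beside 841. Of the genes called at both times, 1 was called in opposite directions, the matrix glycoprotein gene vitronectin (Vtn, -0.52 ± 0.17, adjusted p = 0.0443 at D5, and 0.63 ± 0.17, adjusted p = 0.0287 at D10).

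The fourth comparison set D10 directly against D5. Of 15972 genes 12 were higher and 9 lower at D10 with edgeR's quasi-likelihood test, 11 and 8 of them by a fold of at least 2. Lipoprotein lipase (Lpl) rose from 44.1 ± 4.00 to 144 ± 3.49 CPM (1.71 ± 0.16, adjusted p = 0.00256), insulin-like growth factor 2 (Igf2) from 1024 ± 44.0 to 3561 ± 978 CPM (1.80 ± 0.20, adjusted p = 0.00654) and the cartilage collagen Col2a1 from 9.80 ± 5.35 to 74.0 ± 27.7 CPM (2.91 ± 0.36, adjusted p = 0.0159). The membrane protein gene Vat1l (5.78-fold), the neuronal adhesion gene Ntm (3.98-fold), the collagen IV chain Col4a5 (2.48-fold) and Vtn (2.22-fold) were also higher. Lower at D10 were the carbonic anhydrase Car4 (17 ± 1.38 to 2.21 ± 0.434 CPM, adjusted p = 0.0170), the protease inhibitor Serpina3g (4.48-fold), Fn1 (2.24-fold, adjusted p = 0.0361) and the integrin Itga1 (2.85-fold). So were the pericyte channel genes Abcc9 (3.07-fold) and Kcnj8 (2.83-fold), the muscle filament gene Des (2.18-fold) and the stromal surface gene Cd248 (1.97-fold). The count of 21 depended on single libraries. It was 218 without D10 replicate 3, 6 without D10 replicate 2, 3 without D10 replicate 1, and 4, 14 and 1 without D5 replicates 1, 2 and 3. Of the 15 genes just named, Lpl kept its call whichever library was left out (highest adjusted p 0.0430). Igf2 and Col2a1 lost theirs without D5 replicate 3 (0.0716 and 0.108) and kept them without each of the other libraries. The other 12 lost theirs without D5 replicate 3 (0.108 to 0.191), and most of them also without D5 replicate 1 (11 genes, 0.0568 or more), D5 replicate 2 (11 genes, 0.0509 to 0.121), D10 replicate 1 (12 genes, 0.0668 to 0.212) or D10 replicate 2 (11 genes, 0.0526 to 0.148). In a fit of the compared groups alone only Lpl, Igf2 and Car4 kept their calls. Abcc9, Itga1, Vtn, Col4a5, Fn1 and Cd248 also lost theirs in a fit of all 11 libraries, and Vat1l with limma voom. At an unadjusted p under 0.05, 1353 genes differed, and the libraries did not overlap for 14.1% of genes against 10% by chance.

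Between D10 and D5 no difference was called for Col1a1 (0.31 ± 0.30, adjusted p = 0.844), Col1a2 (0.19 ± 0.27), Col3a1 (-0.01 ± 0.28), Postn (0.47 ± 0.30), Acta2 (-0.70 ± 0.36), Cd74 (-0.23 ± 0.35), H2-K1 (-0.20 ± 0.17) and Ptprc (-0.96 ± 0.40). Mki67 (-1.14 ± 0.31, adjusted p = 0.259) was called lower without D10 replicate 3 (-1.54, 0.0318), as was the pericyte regulator Rgs5 (974 ± 349 to 256 ± 99.5 CPM, adjusted p = 0.0812, 0.0355 without that library). Over the alternatives the adjusted p of Mki67 ran from 0.00215 (without a filter) to 0.797, and that of Rgs5 from 4.63e-07 (without a filter) to 0.258. As lists, G2/M genes were lower at D10 (median log2 -1.20, list adjusted p = 5.73e-26) with 0 of 36 called and 10 adjusted over the list alone. So were mural genes (4 of 14, 8 over the list alone, list adjusted p = 4.05e-17) and T cell genes (0 of 17, 4 over the list alone, -1.18, list adjusted p = 2.62e-14). Basement membrane (1 of 19, 10 over the list alone, 0.49, list adjusted p = 3.04e-13), cartilage and bone (1 of 12, 5 over the list alone, 1.04, list adjusted p = 2.11e-07) and fibroblast identity genes (1 of 24, 8 over the list alone, 0.36, list adjusted p = 6.75e-08) were higher. For all 6 lists adjusted p = 0.15 with an estimated correlation. Pan-leukocyte genes were lower (0 of 14, 1 over the list alone, -0.90, list adjusted p = 7.14e-08, adjusted p = 0.271 with an estimated correlation). Macrophage genes were higher (0 of 20, 1 over the list alone, 0.77, list adjusted p = 5.17e-07, adjusted p = 0.16 with an estimated correlation). Interferon gamma response genes were lower (0 of 29, 0 over the list alone, -0.52, list adjusted p = 1.79e-09, adjusted p = 0.289 with an estimated correlation). Immediate-early genes were higher (0 of 24, 0 over the list alone, 0.68, list adjusted p = 2.43e-07, adjusted p = 0.402 with an estimated correlation).

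Also higher at D10 than at D5 by camera were erythroid (median 2.49, list adjusted p = 2.85e-07), Schwann cell (0.61, 1.92e-05), astrocyte (0.41, 0.00138), cholesterol synthesis (0.31, 0.000723) and oligodendrocyte genes (0.58, 0.0031), oligodendrocyte precursors (0.28, 0.0127) and the unfolded protein response (0.26, 0.0115). The adjusted p ran from 0.16 to 0.423 with an estimated correlation in these lists. Also lower were S phase (-0.33, 6.21e-05), contractile (-0.30, 4.17e-06), class I (-0.22, 0.000864), class II (-0.58, 0.0195) and type I interferon genes (-0.27, 0.0118). So were matricellular (-0.21, 0.0178), adhesion (-0.07, 0.015), neutrophil and monocyte (-0.61, 0.0173), mitochondrial (-0.13, 0.0245) and ribosomal protein genes (-0.19, 0.0173). The adjusted p ran from 0.317 to 0.551 with an estimated correlation in these lists. In these lists 1 matricellular, 1 contractile, 1 neutrophil and monocyte and 2 adhesion genes were called, all lower. The matricellular gene and the neutrophil and monocyte gene are the same gene, Fn1. Adjusted over the list alone, 2 matricellular, 1 contractile, 1 neutrophil and 3 adhesion genes were lower. Higher by that count were 1 adhesion, 2 oligodendrocyte, 2 astrocyte, 2 erythroid and 1 oligodendrocyte precursor gene. Of all 27 lists called by camera, 15 kept their call in each fit without 1 library. Calls were lost without D5 replicate 1 for class II (0.0527), neutrophil (0.388), oligodendrocyte precursor (0.123), mitochondrial (0.0834) and ribosomal genes (0.341). Without D5 replicate 2 they were lost for class II (0.0937), adhesion (0.0745), the unfolded protein response (0.103), neutrophil (0.0642) and mitochondrial genes (0.0552). D5 replicate 3 decided the calls of matricellular (0.0642), unfolded protein response (0.0986), oligodendrocyte (0.0642) and ribosomal genes (0.124). Without D10 replicate 1, class I (0.117), class II (0.0658), type I interferon (0.198), adhesion (0.0518), neutrophil (0.207), oligodendrocyte precursor (0.117), mitochondrial (0.0613) and ribosomal genes (0.177) lost theirs. Without D10 replicate 2 the same happened for matricellular (0.506), class II (0.083), adhesion (0.1), cholesterol (0.313), unfolded protein response (0.124), mitochondrial (0.166) and ribosomal genes (0.106). Without D10 replicate 3 it happened for the unfolded protein response (0.0529) and oligodendrocyte precursors (0.072). By the fry test in limma 0 lists moved in one direction, against 27 by camera.

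Lists not called between D10 and D5 were fibrillar collagen (list adjusted p = 0.488, lower without D10 replicate 3, 0.00138), proteases (0.958), Wnt (0.806), retinoid (0.675), cytokine (0.956), axon guidance (0.307), glycolysis (0.475), neuronal (0.332) and ependymal genes (0.862). Leptomeningeal genes (0.156) were called higher without D5 replicate 1 (0.0268) or D10 replicate 3 (0.00741), and solute transporters (0.101) without the same libraries (0.00912 and 0.008). TGF-beta genes (0.156), NF-kB genes (0.814) and complement genes (0.0576) were called higher without D5 replicate 1 (0.0243, 0.0245 and 0.0167), and complement genes also without D10 replicate 2 (0.0421). Growth factors (0.0567) were called higher without D5 replicate 1 (0.0245), D10 replicate 1 (0.0191) or D10 replicate 2 (0.00643), and endothelial genes (0.153) lower without D5 replicate 2 (0.0288). The median was positive and the test direction negative for fibrillar collagen (0.01), protease (0.04) and retinoid genes (0.03). For NF-kB genes the median was -0.04 and the test direction positive, and for cytokines the median was 0.03 and the mean -0.06. For ependymal genes the median was 0.15 and the mean -0.31. Of the lists not called, growth factors held 1 called gene, and over the list alone 5 growth factors, 2 complement, 2 cytokine, 1 leptomeningeal, 1 protease and 1 axon guidance gene were higher. Lower by that count were 2 endothelial, 1 collagen, 1 protease and 1 cytokine gene.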

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

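The comparisons in this part follow the rule for named genes, and the reading of mural subsets was a test chosen after the result was seen. For 15 named genes the change from control differed between D5 and D10 by the test of D10 against D5. Higher at D10 on the log2 scale were Col2a1 (difference 2.91), Vat1l (2.53), Ntm (1.99), Igf2 (1.80), Lpl (1.71), Col4a5 (1.31) and Vtn (1.15). Lower were Cd248 (-0.98), Des (-1.12), Fn1 (-1.16), Kcnj8 (-1.50), Itga1 (-1.51), Abcc9 (-1.62), Serpina3g (-2.16) and Car4 (-2.94). For Col2a1 the change from control was -3.57 at D5 and -0.66 at D10, and for Lpl it was -1.30 and 0.41. Car4 was 4.05 above control at D5 and 1.10 at D10, and Fn1 2.01 and 0.84. Without D5 replicate 3 edgeR called 1 gene in this comparison, and without D10 replicate 3 it called 218, against 21 with all libraries.

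Smooth muscle and pericyte genes differed in their changes. At D5 the median of 7 smooth muscle genes was -1.29 and that of 8 pericyte genes 0.88, a difference of 2.17 ± 0.30 (SE over genes). From D5 to D10 the medians were -0.50 and -1.43, a difference of -0.93 ± 0.32. At D10 against control both medians were negative (-1.84 and -0.69). A changed share of mural cells as a whole would move both sets alike. At D5, 5 smooth muscle genes were called lower and 0 higher, and 2 pericyte genes higher and 0 lower. Of the 8 pericyte genes only 2 were called, near the share of all genes called at D5 (23.9%). The subsets were also compared after the pattern was seen, so these calls cannot decide on a changed share at D5. From D5 to D10, 0 smooth muscle and 3 pericyte genes were called lower. That difference cannot decide, because the SE treats genes as independent and does not measure the spread between libraries. A changed share may still be part of the cause, since both medians were negative from D5 to D10. A change within 1 of the 2 cell types or in their expression was not tested.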

How the results depend on the processing

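Leaving out 3 abundant genes (mmu-mir-689-2, mt-Rnr1 and mt-Rnr2) was chosen after seeing the data and gave 9264, 3820 and 2103 calls for the control against whole cord, D5 and D10 comparisons. With an estimated correlation camera called 0 lists in each of the 4 comparisons, where fry called 36, 23, 16 and 0 in one direction, and 43, 42, 39 and 14 in either. At an adjusted p under 0.01 the calls were 1998 at D5, 841 at D10, 2 between D10 and D5 and 738 in the overlap. The D10 against D5 count was 265 without a filter, 171 with the DESeq2 Wald test, 33 with limma voom and 3 in a fit of the compared groups alone. Leaving out 1 library gave 5973 (whole cord replicate 1) to 10054 (control replicate 3) genes for control against whole cord, and 2446 (D5 replicate 3) to 3588 (control replicate 3) at D5. It gave 1045 (D10 replicate 3) to 2031 (D10 replicate 2) at D10, 1 (D5 replicate 3) to 218 (D10 replicate 3) between D10 and D5, and 951 to 1800 (D10 replicates 3 and 2) in the overlap. A lone whole cord library was assumed to vary like the other group. Genes not called between D10 and D5 turned direction, with ranges of -0.108 to 0.592 for Col1a1, -0.211 to 0.439 for Col1a2, -0.343 to 0.274 for Col3a1 and -0.148 to 0.069 for Slc1a3. Single values were 0.004 and 0.128 for Col3a1 and 0.062 for Slc1a3. Upper quartile scaling moved the median of all genes from 0.0384 to 0.167 for control against whole cord. No label says that replicate numbers mark pairs. Same-number libraries correlated at -0.0779 to 0.171, and not every library correlated best with its own number. With the number as a block the calls were 7763, 2913, 1626 and 23, with 13 of the last shared with the 21 called without it, and Itga2b at D10, not called, turned from -0.35 to 0.05. For named genes and alternatives together, 18, 24, 85 and 96 calls were lost and 1, 0, 2 and 10 gained in the 4 comparisons. The cause of these changes was not tested. The pseudocount was not varied because counts were tested.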

Other observations

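The tests of leukocyte content, of swapped labels and of gene families, and the reading of the 20 genes of lowest p, were chosen only after the results were seen. Among 175 gene families sorted by name, histone genes rose at D5 in 29 of 52 with 1 lower (median log2 2.16, adjusted p = 7.37e-10, adjusted p = 0.821 with an estimated correlation). At D10 they rose in 12 of 52 (1.36, adjusted p = 1.6e-05, adjusted p = 0.923 with an estimated correlation). Guanylate binding protein genes, which respond to interferon, rose in 9 of 10 at D5 (1.80, adjusted p = 4.58e-09, adjusted p = 0.821 with an estimated correlation) and in 8 of 10 at D10 (1.31, adjusted p = 2.07e-06, adjusted p = 0.923 with an estimated correlation). Reads shared between members of both families leave single members uncertain. Apoe, a lipid carrier named after its values were seen, was higher at D10 than at D5 (1.40 ± 0.19, adjusted p = 0.017).

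Leukocyte and class II transcripts were higher in sorted EAE cells. The pan-leukocyte list had a median of 3.60 at D5 and the T cell list 5.83, which is consistent with leukocytes carried in the sort, and in sorted control 1 of 14 and 1 of 18 of these genes exceeded 5 CPM. The only gate stated is GFP, which would remove cells without it. Interferon gamma and class I transcripts together rose at D10 by 0.703 ± 0.198 times their rise at D5, against 0.517 ± 0.143 for pan-leukocyte and 1.69 ± 0.559 for macrophage genes. For T cell genes the ratio was 0.390 ± 0.0854 and for neutrophil and monocyte genes 0.679 ± 0.161. The leukocyte ratios cover only list members under 5 CPM in sorted control, while the interferon gamma and class I ratio covers all tested members. For these transcripts a rise in sorted fibroblasts and leukocyte content cannot be told apart, because the leukocyte lists span that ratio. For G2/M genes leukocyte content stays open too, since their median change from D5 to D10 (-1.20) was near that of T cell genes (-1.18). Leukocyte content was not tested for protease, cytokine, adhesion, complement, NF-kB, type I interferon, S phase and histone genes.

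D10 replicate 3 lay near the D5 libraries. A swap of labels is argued against, since 0 D5 libraries lay nearer to D10 replicates 1 and 2 than to the other D5 libraries. Over 200 genes chosen without it, its median place between D5 (0) and the other D10 libraries (1) was 0.285, and left-out D5 libraries stood at 0.201, 0.305 and -0.0878. Over the 20 genes of lowest p it stood at 0.61, above their 0.096, 0.296 and -0.141, so a D5 library labelled D10 cannot be told apart from a D10 library that varied. No biological explanation was tested.

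With 3 against 3 libraries there are 10 splits, too few for a share under 0.05, and 1 of 10 splits, the real one, gave as many calls in each of the 3 comparisons. By edgeR it called 3817 genes at D5, 2136 at D10 and 21 between D10 and D5, and the highest other split called 0 in each. By camera it called 25, 23 and 27 lists, and the highest other split 22, 21 and 22. Each other split put libraries of both groups in each arm, so a real difference added to the spread within arms. These splits are therefore no reference without a group difference, and their counts decide nothing about chance.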
